A study of Mus musculus with 20 samples.

How the data were processed

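RNA was sequenced from epithelial cells sorted from small-intestinal crypts of 8-week-old C57BL/6J mice that carried an Lgr5-GFP reporter, which marks crypt stem cells. The mice were Itgb7+/+ (wild type, WT) or Itgb7-/- (knockout, KO). Itgb7 encodes the integrin beta 7 subunit, which pairs with alpha 4 or alpha E on gut-homing and intraepithelial lymphocytes. Per the labels' protocols, crypts were released with EDTA, dissociated with TrypLE, and sorted as viable EpCAM+ cells negative for CD45, CD31 and TER119. GFP-high cells were taken as stem cells and GFP-low cells as transit-amplifying (TA) cells. RNA was extracted with a column kit for small inputs, and libraries followed standard Illumina protocols, with strand not given in the sources used here.

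The 20 libraries formed 4 groups of 5, set by the genotype and population named in the labels. WT mice were numbered 1, 3, 6, 7 and 8 and KO mice 2, 3, 4, 5 and 6. The authors deposited 1 table of expected counts per gene for the GFP-high libraries and 1 for the GFP-low libraries. The deposited expected counts carried no normalization that the column totals showed. Per the submitters' processing notes, TopHat2, Bowtie2 and RSEM were used with mouse build mm10; their versions and roles are not given in the sources used here. RSEM shares reads that match several genes between them, so near-identical genes such as the Paneth cell defensins are uncertain individually.

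For GFP-high libraries 11746 gene entries were given, and 11779 for GFP-low libraries. The lowest mean count of any entry was 17.0 and 16.8, so genes of lower count are not analysed here. Of the values, 13.7% in each population were not whole numbers, and all were rounded to whole counts. Spreadsheet conversion had altered 16 and 17 gene names to dates. Another 34 and 30 entries shared a name with a further entry. These were tested separately within a table and left out of comparisons between populations, for which 11296 genes were held by both tables. Positions came from GENCODE release M21 on GRCm38, the assembly also called mm10, in which 11579 and 11615 symbols had a unique match. Overlapping and antisense genes cannot be told apart without strand.

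Library totals ran from 20900404 to 27838392 counts. No libraries were identical, and the smallest chi-square per gene between libraries of the same group was 19.4, far above counting noise.

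Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. TMM factors, filterByExpr at its default minimum count of 10 and Benjamini-Hochberg adjustment at 0.05 were used, without a block. KO was compared with WT within each population on its 10 libraries. GFP-low was compared with GFP-high within each genotype on 10 libraries, and the difference between the KO effects in the populations was fitted as an interaction over all 20. Errors of log2 fold changes are standard errors (SE) from the F statistic, and errors of levels are standard deviations (SD). Levels in CPM were scaled over the libraries and genes of each comparison. The level of a gene in the same group therefore differs between comparisons, and from figures scaled over all 20 libraries.

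Of 35 gene lists, 31 had at least 5 tested members. They covered epithelial lineages, signalling, cell cycle, immune response, metabolism, other cell types and RNA quality. Some lists shared members, so their results are not independent. Also in another list were 11 of 16 secretory progenitor, 11 of 29 stem cell and 12 of 34 Wnt genes. Each was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with the correlation estimated from the data as an alternative and fry beside it. Lists of B and plasma cells (2 and 3 members in the tables), stroma and endothelium (2 and 1), erythroid cells (0 and 0) and sex chromosome genes (4 and 3) were too small. Mean log2 CPM of each list per library, with a prior count of 2, was compared by two-sided exact permutation of the libraries, for which the smallest possible p was 0.00794.

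The groups, tests, lists and naming rule were chosen before the data were examined. Named genes were Itgb7 and Lgr5; the 8 largest rises and falls among passing genes with a mean log2 CPM of at least 3; and members of each described list with the smallest p. Unnamed gene models, pseudogenes and sex chromosome genes were left out of the largest rises and falls. Where no gene passed these criteria, the 10 genes with the smallest p were given, and for the interaction 5, in both cases with unnamed gene models included.

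The pipeline was tested on simulated counts with 200 changed genes per comparison. The changed genes had a mean above 2 CPM. So many changes at once ease the adjusted threshold, so a lone changed gene would be recovered less often. For KO against WT in GFP-high cells, 2% of genes changed 1.25-fold, 40% of those changed 1.5-fold, 82% of those changed 2-fold and 92% of those changed 3-fold were recovered. In GFP-low cells these shares were 2%, 22%, 82% and 94%. For GFP-low against GFP-high they were 2%, 30%, 80% and 100% in WT and 8%, 56%, 96% and 96% in KO. For the interaction they were 2%, 6%, 72% and 88%. False calls made up 3.57%, 2.91%, 2.75%, 5.88% and 2.33% of calls in the same order. A list shifted 1.25-fold in independent genes was recovered in each of the 4 comparisons of groups. In addition, 1 list that was not shifted was called for KO against WT in GFP-high cells and 1 for GFP-low against GFP-high in WT. All simulated genes were drawn independently, so these counts do not cover false calls among correlated members of a list. When the real libraries were divided in other ways, medians of 11 lists in GFP-high and 13 in GFP-low cells passed at the preset correlation.

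Replicate numbers were checked for pairing from the deviations of libraries from their group means. GFP-high and GFP-low libraries of the same number correlated in 10 of 10 pairs (r 0.169 to 0.625 across genes, which are not independent), each best with its own number. Detection of Y-linked transcripts matched in 10 of 10 pairs. The numbers therefore paired populations of the same mouse.

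Alternatives were RLE factors, no filter, a minimum count of 30, DESeq2 1.42.0, limma-voom, robust dispersion, a replicate block, all 20 libraries in 1 fit, an estimated correlation and leaving out each library. Library totals without factors, sex as a covariate, permutation of list means, and the replicate block with an estimated correlation were added after the data were seen. Splits of the samples were drawn at most 100 times.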

Results

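Transcript levels were measured by RNA sequencing in GFP-high and GFP-low cells of the small intestine. The labels name these as stem cells and transit-amplifying cells. The mice, 5 Itgb7+/+ (WT) and 5 Itgb7-/- (KO), carried Lgr5-GFP. Both populations came from each mouse, giving 20 libraries in 4 groups of 5. Total counts ran from 21717749 to 26724362 in WT GFP-high, 20986069 to 27083283 in KO GFP-high, 21465693 to 23182256 in WT GFP-low and 20900404 to 27838392 in KO GFP-low libraries. Itgb7, the targeted gene, was in neither table and is not analysed here, so the genotype labels could not be checked against it. Y-linked transcripts were detected in 3 of 5 mice of each genotype.

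The first comparison asked how GFP-low cells differed from GFP-high cells of WT mice. Transcripts of stem cells were lower in GFP-low cells, and those of absorptive and secretory cells were higher. Lgr5, a receptor that amplifies Wnt signals and drives the reporter, fell from 98.2 ± 19.3 to 12.5 ± 6.48 CPM (mean ± SD, n = 5), a log2 fold change of -2.97 ± 0.33 (SE). Zg16, a lectin-like protein of goblet cell granules, rose from 831 ± 344 to 17304 ± 7205 CPM, a log2 fold change of 4.38 ± 0.35. Of 11293 genes tested with edgeR, 4901 changed at an adjusted p under 0.05, 2479 upward and 2422 downward.

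Of the 28 measured genes of the intestinal stem cell list, 26 fell and 2 did not pass, with a median log2 fold change of -1.79. The count was also 26 adjusted over the list alone. The falls included Ascl2, a transcription factor that maintains stem cells (-2.33 ± 0.13), the Wnt pathway modulator Igfbp4 (-2.40 ± 0.12), Smoc2 (-1.66 ± 0.11) and the ion cotransporter Slc12a2 (-1.67 ± 0.10). The largest falls among expressed genes held by both tables were those of Fstl1 (-3.06 ± 0.34), Lgr5, Cyp2e1 (-2.83 ± 0.38) and Tnfrsf19 (-2.80 ± 0.27). Next came Slc1a2 (-2.78 ± 0.33), Gkn3 (-2.74 ± 0.19), Rassf5 (-2.61 ± 0.21) and Olfm4 (-2.55 ± 0.23). Tnfrsf19 is a Wnt target, and Gkn3 and Olfm4 are stem cell markers. Among 25 Wnt target and pathway genes 14 fell, 4 rose and 7 did not pass, and the same numbers were obtained adjusted over the list alone. Axin2, a feedback inhibitor of the pathway, fell by 1.97 ± 0.16 on the log2 scale, and the adhesion receptor Cd44 fell by 1.81 ± 0.15. The stem cell list (camera adjusted p = 2.91e-39; adjusted p = 0.0105 with an estimated correlation) and the Wnt list (1.03e-07; adjusted p = 0.0105 with an estimated correlation) passed in both forms of the test. With the replicate block that paired the populations of each mouse, the adjusted p was 0.0912 and 0.0991 with an estimated correlation.

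Proliferation genes were moderately lower. In the S phase list 34 of 46 genes fell and 12 did not pass (median -0.56), including the replication licensing factor Mcm2 (-0.86 ± 0.12) and Cdca7 (-1.96 ± 0.15). In the G2/M list 41 of 55 fell and 14 did not pass (median -0.54), including Psrc1 (-1.83 ± 0.18) and the nuclear envelope protein Tmpo (-0.68 ± 0.10). Ribosomal protein transcripts fell in 47 of 65 cases and did not pass in 18 (median -0.45), with Rpl3 at -0.67 ± 0.12. The falls numbered 34, 46 and 51 adjusted over the list alone. The 3 lists passed at the preset correlation (camera adjusted p = 1.20e-09, 2.11e-09 and 3.08e-08), but the adjusted p was 0.281, 0.364 and 0.497 with an estimated correlation.

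Absorptive enterocyte genes rose in 36 of 39 cases and 3 did not pass, with a median of 2.15 (camera adjusted p = 4.75e-38; adjusted p = 0.0220 with an estimated correlation). That count was 36 as well adjusted over the list alone. With the replicate block the list's adjusted p was 0.0730 with an estimated correlation. Members with the smallest p were the glutathione transferase Gsta1 (4.85 ± 0.20), the retinol-binding protein Rbp2 (4.53 ± 0.25), the fructose transporter Slc2a5 (2.19 ± 0.12) and Krt20, a keratin of differentiated cells (3.78 ± 0.20). The largest rises among expressed genes held by both tables were those of Ggt1 (4.95 ± 0.40), Gsta1, the dipeptidase Dpep1 (4.58 ± 0.45) and Rbp2. Next came the lipoprotein component Apoa1 (4.53 ± 0.37), the bile acid-binding protein Fabp6 (4.42 ± 0.57), Zg16 and Reg1 (4.34 ± 0.25). Regional lists moved upward in both directions of the gut axis. Of 10 proximal genes 7 rose and 3 did not pass, including the iron exporter Slc40a1 (2.46 ± 0.20), and of 11 distal genes 7 rose and 4 did not pass, including the bile acid transporter subunit Slc51a (3.49 ± 0.22). Both counts stayed at 7 adjusted over the list alone. Their camera adjusted p-values were 1.20e-09 and 4.30e-07, and the adjusted p was 0.00530 and 0.0402 with an estimated correlation, or 0.0558 and 0.0345 with the replicate block as well.

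Secretory lineages were also higher in WT GFP-low cells. In the goblet list 23 of 25 genes rose, 1 fell and 1 did not pass (median 2.51), with Clca1 at 3.90 ± 0.34 and Capn9 at 3.51 ± 0.33. Enteroendocrine genes rose in 21 of 23 cases (median 2.17), including the hormone precursor Gcg (2.88 ± 0.30) and the granin Chga (2.90 ± 0.34). In the tuft list 15 of 16 rose (median 1.70), with the leukotriene C4 synthase Ltc4s at 1.80 ± 0.33. In the Paneth list 25 of 25 rose (median 2.19), with Mptx1 at 2.97 ± 0.33 and the lysozyme Lyz2 at 2.19 ± 0.44. The rises in these lineages numbered 24, 22, 15 and 25 adjusted over the list alone. Paneth transcripts took 16.1% ± 7.70 of counts in WT GFP-low and 4.97% ± 2.64 in WT GFP-high libraries (SD, n = 5). With such transcripts present, the GFP-low population cannot be read as transit-amplifying cells only. These 4 lists passed camera (adjusted p = 1.42e-18, 3.66e-11, 8.96e-05 and 3.95e-08), while the adjusted p was 0.153, 0.281, 0.410 and 0.364 with an estimated correlation.

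Endoplasmic reticulum and lipid genes followed the same direction. Unfolded protein response genes rose in 24 of 26 cases (median 1.12), including the chaperone Hspa5 (1.30 ± 0.13) and Manf (1.84 ± 0.23). Cholesterol biosynthesis genes rose in 21 of 25 cases (median 0.88), including Fdps (1.37 ± 0.24), and glycolysis genes in 10 of 18 with 1 fall (median 0.55), including Pfkp (2.43 ± 0.13). Epithelial innate defence genes rose in 14 of 21 cases (median 1.58), including the antimicrobial lectin Reg3a (3.63 ± 0.43), and interferon response genes in 18 of 36 with 1 fall (median 0.59), including Irf7 (1.63 ± 0.19). Adjusted over the list alone, the rises numbered 25, 23, 12, 15 and 20. The camera adjusted p was 3.13e-10, 9.73e-07, 4.72e-05, 9.73e-07 and 2.13e-04, and the adjusted p was 0.153, 0.364, 0.153, 0.0421 and 0.364 with an estimated correlation (innate defence 0.0912 with the replicate block as well).

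Further lists that passed were fetal and regenerative genes (7 of 9 rose and 1 fell; median 0.62; Anxa3 3.55 ± 0.36), oxidative phosphorylation (21 of 65 rose; median 0.22; Cycs 0.75 ± 0.14) and fatty acid oxidation and PPAR targets (10 of 27 rose and 3 fell; median 0.32; Fabp2 1.91 ± 0.12). In these 3 lists 7, 18 and 13 rose adjusted over the list alone. Dissociation stress genes, a sign of cell handling, rose in 8 of 26 cases and 1 fell (median 0.75; Klf4 1.33 ± 0.35), with the same rises adjusted over the list alone. The camera adjusted p was 0.0210, 0.00255, 0.0155 and 0.0391, and the adjusted p was 0.281, 0.603, 0.603 and 0.616 with an estimated correlation. The dissociation stress call was lost without the GFP-high library of mouse 3, 7 or 8 or the GFP-low library of mouse 1, 6 or 8 (median 0.55 to 0.79), and the fatty acid oxidation and PPAR target call without the GFP-high library of mouse 1 (0.24). MHC class II genes did not pass as a list (median -1.03, camera adjusted p = 0.108), although 3 of 8 fell, among them Cd74 (-1.31 ± 0.46). With the replicate block, the MHC class II list passed at the preset correlation (median -1.06, camera adjusted p = 0.00121; adjusted p = 0.3995 with an estimated correlation). Neither T cell and intraepithelial lymphocyte genes (median -0.36, adjusted p = 0.463), myeloid genes (0.08, 0.618) nor mitochondrially encoded genes (-0.02, 0.957) passed camera. In the Notch list, which did not pass (adjusted p = 0.258), the median was 0.03 while the mean and the test pointed downward, and in the mitochondrial list the mean was 0.03 while the median and the test pointed downward.

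**Figure D1:**
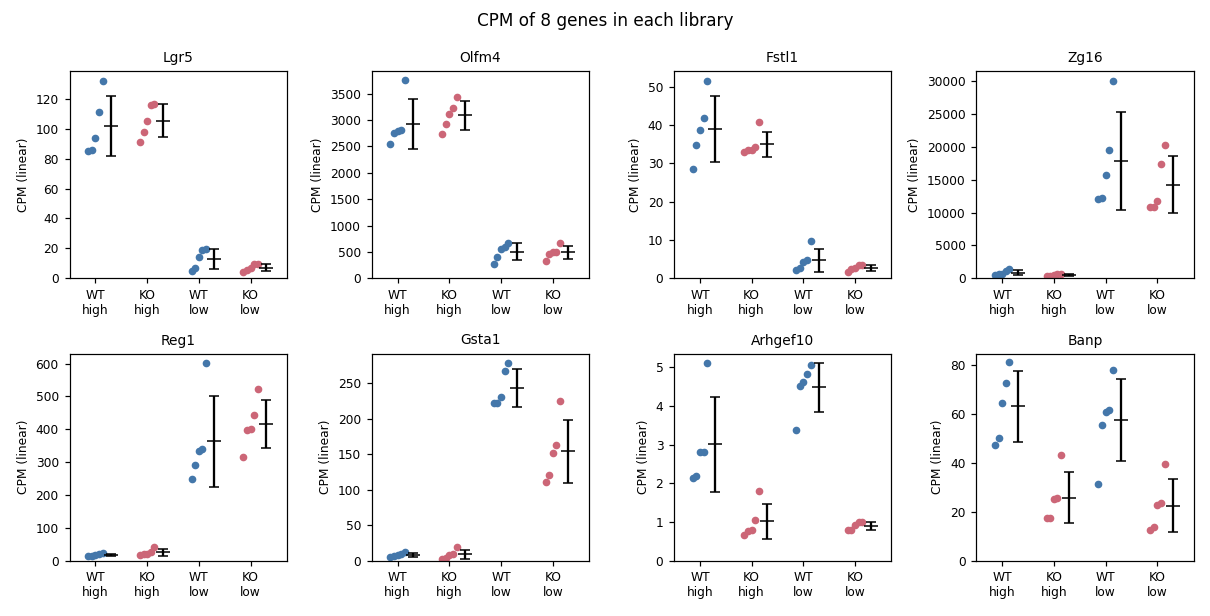
CPM on a linear axis for 8 genes in WT and KO GFP-high and GFP-low libraries, scaled over all 20 libraries together; points are libraries (5 per group) and black marks are means with SD. Lgr5 averaged 101.7 and 105.4 CPM in WT and KO GFP-high libraries and 12.9 and 7.00 CPM in WT and KO GFP-low libraries, while Arhgef10 averaged 4.48 in WT GFP-low and 0.906 in KO GFP-low libraries.

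The same comparison in KO mice gave 5707 changed genes of 11294 tested with edgeR, 2956 upward and 2751 downward. Lgr5 fell from 109 ± 11.7 to 7.28 ± 2.49 CPM (SD, n = 5), a log2 fold change of -3.91 ± 0.20 (SE), followed by Fstl1 (-3.67 ± 0.17), Tnfrsf19 (-3.54 ± 0.30), Cyp2e1 (-3.51 ± 0.33), Slc1a2 (-3.49 ± 0.22), Gkn3 (-3.35 ± 0.17), the urea transporter Slc14a1 (-2.72 ± 0.18) and Pimreg (-2.66 ± 0.27). The largest rises were those of Zg16 (4.95 ± 0.28), the incretin hormone Gip (4.62 ± 0.23), Clca1 (4.45 ± 0.44), Capn9 (4.32 ± 0.29), the mucus protein Fcgbp (4.22 ± 0.25), Gsta1 (4.13 ± 0.45), the hormone Sst (4.10 ± 0.47) and Reg1 (4.03 ± 0.23).

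In KO mice the stem cell list again had 26 of 28 genes lower (median -1.92), with Axin2 at -2.33 ± 0.10 and Rnf43, an E3 ligase that removes Wnt receptors, at -1.79 ± 0.09. Of 25 Wnt genes 16 fell and 3 rose (median -0.68), among them Ascl2 at -2.46 ± 0.13. These counts stayed at 26 and 16 adjusted over the list alone. The adjusted p was 0.00440 for the stem cell list and 0.00399 for the Wnt list with an estimated correlation, against 2.36e-49 and 3.77e-12 in camera at the preset value. In the G2/M list 48 of 55 genes fell (median -0.63; Psrc1 -2.05 ± 0.11), in the S phase list 30 of 46 fell and 1 rose (median -0.48; Cdca7 -1.87 ± 0.11), and in the ribosomal protein list 51 of 65 fell (median -0.39; Rps19 -0.61 ± 0.09). Adjusted over the list alone, the falls numbered 50, 31 and 56. Camera gave an adjusted p of 9.52e-13, 8.42e-06 and 6.08e-08, and the adjusted p was 0.316, 0.397 and 0.397 with an estimated correlation.

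Enteroendocrine genes rose in 23 of 23 cases in KO mice (median 3.17; Ghrl 3.11 ± 0.19), goblet genes in 24 of 25 with 1 fall (median 2.72; Rep15 3.67 ± 0.24), tuft genes in 13 of 16 (median 2.34; the tuft kinase Dclk1 3.32 ± 0.25) and Paneth genes in 25 of 25 (median 1.55; Mptx1 3.11 ± 0.52). Paneth transcripts took 10.8% ± 4.42 of counts in KO GFP-low and 4.62% ± 1.49 in KO GFP-high libraries (SD, n = 5). Secretory progenitor genes rose in 10 of 15 cases and 3 fell (median 1.91; the Notch ligand Dll4 2.06 ± 0.19, the progenitor factor Sox4 -1.58 ± 0.10). In WT mice this list did not pass (8 of 15 rose, 3 fell; median 0.88, camera adjusted p = 0.102). Absorptive enterocyte genes rose in 35 of 39 cases with 1 fall (median 2.09; Mep1b 2.89 ± 0.19). Adjusted over the list alone, the rises numbered 23, 24, 13, 25, 11 and 35. In camera the adjusted p was 1.18e-22, 9.70e-22, 5.44e-07, 5.24e-05, 0.0132 and 3.06e-20, and the adjusted p was 0.0703, 0.0968, 0.316, 0.518, 0.509 and 0.0714 with an estimated correlation.

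Among the remaining lists in KO mice, unfolded protein response genes rose in 24 of 26 cases (median 1.19; Xbp1 1.53 ± 0.12), proximal genes in 8 of 10 (2.28; Adh6a 2.48 ± 0.18) and innate defence genes in 16 of 21 (1.59; Il18 2.34 ± 0.15). Camera gave 8.84e-16, 2.21e-08 and 2.75e-07 for these, and the adjusted p was 0.0361 for each with an estimated correlation. With the replicate block as well, the unfolded protein response list missed the threshold (0.111), while the enterocyte and glycolysis lists passed (0.0381 each). Cholesterol biosynthesis genes rose in 24 of 25 cases (median 1.03; Hmgcs1 1.35 ± 0.12), glycolysis genes in 15 of 18 (0.71; Ldha 1.27 ± 0.10), distal genes in 8 of 11 (1.84; Pyy 3.52 ± 0.30), interferon response genes in 19 of 36 with 3 falls (0.50; Irf7 1.87 ± 0.14) and oxidative phosphorylation genes in 33 of 65 (0.25; Cox6a1 1.53 ± 0.25). Camera gave 7.68e-11, 3.86e-06, 3.65e-04, 0.00224 and 0.00205 for these 5 lists, and the adjusted p was 0.0769, 0.0703, 0.187, 0.328 and 0.570 with an estimated correlation. Fetal and regenerative genes rose in 7 of 9 cases with 2 falls (0.65; Anxa3 3.51 ± 0.33; camera adjusted p = 0.0321; adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone, the rises of these 9 lists numbered 24, 8, 16, 24, 15, 8, 19, 34 and 7. Dissociation stress genes rose in 19 of 26 cases and 2 fell (0.72; Dnajb1 1.81 ± 0.13; camera adjusted p = 7.38e-05; adjusted p = 0.303 with an estimated correlation), with 19 rises adjusted over the list alone. MHC class II genes fell in 5 of 8 cases, and the list did not pass (median -0.99, camera adjusted p = 0.0600) without the replicate block but did with it at the preset correlation (-1.04, camera adjusted p = 5.86e-06; adjusted p = 0.111 with an estimated correlation). Fatty acid oxidation and PPAR targets did not pass either (0.20, adjusted p = 0.136). In the mitochondrial list, which did not pass (0.822), the median and the test pointed downward and the mean upward.

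In both genotypes 2219 genes rose and 1969 fell, where 649 and 590 would be shared if the calls were independent, and 0 moved in opposite directions. Across 11292 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.937. Scaled by library totals alone, the median of all genes was -0.37 in WT and -0.27 in KO mice, and the calls divided into 1188 rises and 4895 falls in WT and 1778 and 4738 in KO mice; the directions above are relative to that shift. With that scaling the medians of oxidative phosphorylation (-0.14 and -0.00106) and of fatty acid oxidation and PPAR targets (-0.02 and -0.06) were below 0. Medians of the interferon response (0.20 and 0.23), glycolysis (0.20 and 0.46), fetal and regenerative (0.29 and 0.38) and dissociation stress lists (0.43 and 0.46) were smaller by over 1.5 times in WT and KO mice, as were those of cholesterol biosynthesis (0.51) and the unfolded protein response (0.74) in WT mice. Falls were larger by over 1.5 times for S phase (-0.91 and -0.73) and ribosomal protein genes (-0.79 and -0.64) in both genotypes, and for Wnt (-1.02) and G2/M genes (-0.90) in WT mice.

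**Figure D2:**
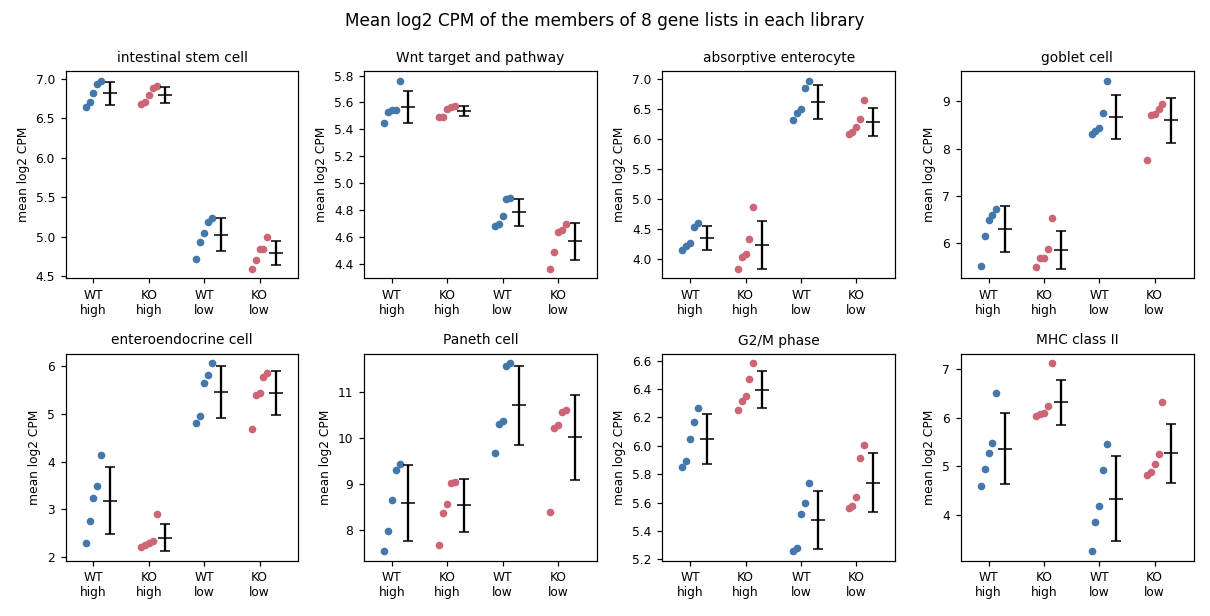
Mean log2 CPM of the members of 8 gene lists in WT and KO GFP-high and GFP-low libraries, scaled over all 20 libraries together; points are libraries (5 per group), black marks are means with SD, and the vertical axes do not start at 0. The stem cell list averaged 6.82 and 6.79 in WT and KO GFP-high libraries and 5.02 and 4.80 in WT and KO GFP-low libraries, and the G2/M list averaged 6.05 in WT GFP-high and 6.40 in KO GFP-high libraries.

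The next comparison asked what loss of Itgb7 changed in GFP-high cells. Paneth transcripts took on average 4.97% of counts in WT and 4.62% in KO GFP-high libraries, so these libraries cannot be read as stem cells only. Mitotic and MHC class II transcripts were higher and secretory lineage transcripts lower in KO cells as lists at the preset correlation, while no single gene passed. Of 31 lists 12 passed at that correlation and 0 with an estimated correlation. Lgr5 was at 113 ± 22.1 CPM in WT and 117 ± 12.9 CPM in KO cells (SD, n = 5), a log2 fold change of 0.06 ± 0.12 (SE; edgeR adjusted p = 0.932). Of 11745 genes, edgeR called 0 changed (1150 at an unadjusted p under 0.05), limma-voom 0, and DESeq2 145, of which 50 were higher and 95 lower. The 10 genes with the smallest p shared an edgeR adjusted p of 0.163 and did not pass. They were Ss18l2 (0.69 ± 0.12), Tm4sf4 (-0.79 ± 0.14), Banp (-1.29 ± 0.23), Zkscan7 (1.35 ± 0.24), Hmmr (0.52 ± 0.10), Nek2 (0.60 ± 0.11), Fam57a (-0.70 ± 0.13), the transcription factor Nfib (0.70 ± 0.13), Manf (-0.70 ± 0.14) and the sulfotransferase Chst2 (-1.61 ± 0.32). Without KO mouse 2, Banp, a nuclear matrix-associated DNA-binding protein, passed alone at -1.55 ± 0.19 (edgeR adjusted p = 0.0170; over the alternatives its adjusted p ran from 6.75e-08 to 0.371).

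In GFP-high cells the G2/M list was higher in KO mice, with a median log2 fold change of 0.37 and 53 of 55 genes above 0. None of its genes passed over all genes, and 43 rose when adjusted over the list alone. Hmmr, a spindle protein, was at 49.6 ± 6.53 CPM in WT and 71.0 ± 4.75 CPM in KO cells, and the centrosomal kinase Nek2 at 29.4 ± 4.52 and 44.3 ± 3.26 CPM (SD, n = 5). Ckap2 (0.60 ± 0.12) and Dlgap5 (0.69 ± 0.14) had similar values. The list's camera adjusted p was 1.34e-39, and the adjusted p was 0.343 with an estimated correlation. S phase genes did not pass (median -0.02, adjusted p = 0.427).

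Secretory lineage lists were lower in KO GFP-high cells at the preset correlation. Enteroendocrine genes had a median of -0.94 with 22 of 23 below 0, including the transcription factor Isl1 (-1.37 ± 0.30), Pyy (-1.37 ± 0.36) and Chgb (-1.04 ± 0.30). Tuft genes had a median of -0.58 with 14 of 16 below 0, including Alox5ap (-1.68 ± 0.33), the actin regulator Avil (-1.18 ± 0.27) and Dclk1 (-1.58 ± 0.36). Goblet genes had a median of -0.48 with 24 of 25 below 0, including Foxa3 (-0.53 ± 0.12), Zg16 (-0.88 ± 0.26) and Tff3 (-0.77 ± 0.26). Secretory progenitor genes had a median of -0.39 with 14 of 15 below 0, including Neurog3, which starts the enteroendocrine fate (-1.08 ± 0.33). Of these members, 0 passed over all genes, and 7, 6, 1 and 2 fell when adjusted over the list alone. Camera gave an adjusted p of 2.76e-13, 2.99e-08, 3.04e-09 and 3.71e-05, and the adjusted p was 0.343, 0.343, 0.463 and 0.360 with an estimated correlation. Without WT mouse 1 the enteroendocrine median was -0.55, and the secretory progenitor median was -0.22 without WT mouse 3 and -0.58 without WT mouse 7. Paneth genes did not pass (-0.17, adjusted p = 0.427), and neither did enterocyte genes (-0.06, 0.283), stem cell genes (-0.01, 0.946) or adherens junction genes (camera adjusted p = 0.470).

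Unfolded protein response genes had a median of -0.14 in KO GFP-high cells, with 22 of 26 below 0. Manf, Herpud1 (-1.13 ± 0.23), Hspa5 (-0.41 ± 0.09) and 1 more fell when adjusted over the list alone (camera adjusted p = 1.22e-05; adjusted p = 0.343 with an estimated correlation). The unfolded protein response median was -0.0799 without WT mouse 1 and -0.24 without WT mouse 7. MHC class II genes, which present antigen to CD4 T cells, were above 0 in 8 of 8 cases with a median of 0.85, and 5 rose when adjusted over the list alone. The invariant chain Cd74 was at 209 ± 130 CPM in WT and 478 ± 205 CPM in KO cells (log2 fold change 1.19 ± 0.35), and H2-Aa had a log2 fold change of 1.43 ± 0.50. The interferon response list was also higher (median 0.21, 33 of 38 above 0, 2 rises adjusted over the list alone), with the immunoproteasome subunit Psmb9 at 0.46 ± 0.12 and the peptide transporter Tap1 at 0.50 ± 0.13. Markers of T cells and intraepithelial lymphocytes, which the gate should remove, moved in the same direction (median 0.80, 9 of 9 above 0), with Nkg7 at 1.28 ± 0.60 and the granzyme Gzma at 0.99 ± 0.51. Camera gave 2.54e-07, 1.34e-06 and 8.11e-04 for these 3 lists, and the adjusted p was 0.343, 0.360 and 0.483 with an estimated correlation. KO mouse 4 had an MHC class II score of 7.28, against 6.18 to 6.39 in the other KO mice. The MHC class II median was 0.60 without KO mouse 4 and 1.29 without WT mouse 6, and without WT mouse 7 the T cell and intraepithelial lymphocyte median was 0.53. Myeloid genes did not pass (0.14, adjusted p = 0.119).

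Ribosomal protein (median -0.09), fatty acid oxidation and PPAR target (-0.15) and cholesterol biosynthesis (0.15) genes passed at the preset correlation without any member passing, over all genes or adjusted over the list alone. Examples were Rpl27 (-0.26 ± 0.08), the nuclear receptor Ppara (-0.63 ± 0.18) and Mvk (0.31 ± 0.15), with an adjusted p of 0.888, 0.821 and 0.855 with an estimated correlation. The ribosomal protein median was -0.0526 when scaled by library totals, and the list lost its call without WT mouse 7 (median -0.06) or 8 (-0.03). The fatty acid oxidation and PPAR target list lost its call without WT mouse 6, 7 or 8 or KO mouse 2, 3 or 6 (-0.17 to -0.06), and the cholesterol biosynthesis list without WT mouse 6, 7 or 8 or KO mouse 2 or 6 (0.07 to 0.09). Without WT mouse 3 the cholesterol biosynthesis median was 0.24 and the ribosomal protein median -0.16. Dissociation stress genes (-0.11, camera adjusted p = 0.143) and mitochondrially encoded genes (adjusted p = 0.992) did not pass. Median, mean and test differed in sign in the adherens junction, proximal, Wnt, mitochondrial, p53 and glycolysis lists, none of which passed. By exact permutation of list means (n = 5 per group), G2/M (p = 0.0159), tuft (p = 0.0238), MHC class II (p = 0.0397) and interferon response (p = 0.0476) were under 0.05 before adjustment and 0 of 31 lists after it.

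In GFP-low cells 1 of 11778 genes changed between genotypes. Arhgef10, at chromosome 8, 14911663 to 15001085 (mm10, ENSMUSG00000071176), fell from 4.02 ± 0.586 CPM in WT to 0.813 ± 0.0911 CPM in KO cells (SD, n = 5). Its log2 fold change was -2.30 ± 0.21 (edgeR adjusted p = 6.90e-04), and the 5 KO values lay below the 5 WT values. In GFP-high cells it was at 3.34 ± 1.37 and 1.13 ± 0.508 CPM, a log2 fold change of -1.56 ± 0.34 that did not pass (edgeR adjusted p = 0.167). At an unadjusted p under 0.05 there were 744 genes in GFP-low cells, limma-voom called 1 gene and DESeq2 12, of which 1 was higher and 11 lower. The next genes did not pass and were Gm26620 (-1.72 ± 0.29), the transcription factor Sox9 (-0.71 ± 0.13), Rab4a (-0.68 ± 0.13), Gm3776 (-0.79 ± 0.16), Gif (-2.18 ± 0.45), Gm44215 (0.78 ± 0.17), Gstm3 (-0.78 ± 0.17), Fhit (-0.78 ± 0.17) and Banp (-1.36 ± 0.30). Their edgeR adjusted p ran from 0.241 to 0.490. Of 31 lists 17 passed at the preset correlation and 0 with an estimated correlation. Without KO mouse 4, Gm3776 passed as a further gene (-0.98 ± 0.13, edgeR adjusted p = 0.0302; 0.00796 to 0.994 over the alternatives).

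Lgr5 was at 11.6 ± 5.98 CPM in WT and 6.28 ± 2.14 CPM in KO GFP-low cells (SD, n = 5), a log2 fold change of -0.89 ± 0.36 that did not pass (edgeR adjusted p = 0.752). At the preset correlation the stem cell list was lower in KO GFP-low cells (median -0.16, 21 of 28 below 0), with Gkn3 at -0.71 ± 0.22 and Ascl2 at -0.47 ± 0.17. The Wnt list was lower as well (median -0.15, 19 of 25 below 0), with Sox9, Myc (-0.71 ± 0.18) and the Wnt receptor-removing ligase Znrf3 (-0.45 ± 0.17), although when scaled by library totals the Wnt median was 0.00339 and the stem cell median -0.0138. That scaling moved the median of all genes to 0.14. Of these members 0 passed over all genes, and 1 and 2 fell when adjusted over the list alone. Camera gave 2.99e-04 and 2.41e-04, and the adjusted p was 0.491 and 0.0625 with an estimated correlation. The stem cell median was -0.25 without WT mouse 8 and -0.27 without KO mouse 3, and the Wnt median was -0.09 without KO mouse 2.

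Absorptive and Paneth transcripts were lower in KO GFP-low cells at the preset correlation. Enterocyte genes had a median of -0.31 (-0.147 when scaled by library totals) with 41 of 44 below 0, and 3 fell when adjusted over the list alone. They were the fatty acid-binding proteins Fabp1 (-1.10 ± 0.25) and Fabp2 (-0.48 ± 0.13) and Gsta1 (-0.66 ± 0.17). Fatty acid oxidation and PPAR targets had a median of -0.30 (-0.17 when scaled by library totals) with 26 of 28 below 0 and 7 falls adjusted over the list alone, among them Cyp4a10 (-1.59 ± 0.43) and Creb3l3 (-0.93 ± 0.28). Proximal genes had a median of -0.11 (0.03 when scaled by library totals) with 2 falls adjusted over the list alone, among them Fabp1. Paneth genes had a median of -0.74 with 24 of 25 below 0 and 0 falls adjusted over the list alone, with Defa26 at -1.72 ± 0.62 and Clps at -0.89 ± 0.38. The camera adjusted p was 9.90e-14, 3.97e-11, 0.00573 and 6.80e-10, and the adjusted p was 0.374, 0.374, 0.374 and 0.545 with an estimated correlation. KO mouse 2 had a Paneth cell score of 8.22, against 10.1 to 10.5 in the other KO mice. The Paneth cell median was -0.51 without KO mouse 2 (camera adjusted p = 0.00103) and -0.47 without WT mouse 3. The fatty acid oxidation and PPAR target median was -0.17 without WT mouse 6, and the proximal small intestine median ran from -0.31 without KO mouse 4 to -0.00329 without WT mouse 7. Goblet (median 0.03, adjusted p = 0.728), enteroendocrine (-0.01, 0.862), tuft (-0.27, 0.0786) and secretory progenitor genes (0.04, 0.924) did not pass.

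G2/M genes were higher in KO GFP-low cells at the preset correlation (median 0.25, 52 of 55 above 0, 1 rise adjusted over the list alone), with Nek2 at 0.55 ± 0.12 and the cyclin Ccna2 at 0.47 ± 0.14. MHC class II genes were above 0 in 8 of 8 cases (median 0.91, 2 rises adjusted over the list alone), with H2-Ab1 at 1.04 ± 0.33 and Cd74 at 1.22 ± 0.41. When scaled by library totals, the medians of G2/M (0.40), cholesterol biosynthesis (0.33) and interferon response genes (0.32) were larger. Without KO mouse 4 the MHC class II median was 0.49, and its camera adjusted p moved from 2.97e-07 to 1.59e-04. Cholesterol biosynthesis genes were above 0 in 25 of 25 cases (median 0.18; Dhcr7 0.31 ± 0.12), and interferon response genes in 26 of 43 (0.16; Psmb8 0.49 ± 0.13). Markers of T cells and intraepithelial lymphocytes were above 0 in 9 of 9 cases (median 0.62; Gzmb 1.08 ± 0.55). For these 5 lists camera gave 7.45e-17, 2.97e-07, 3.58e-06, 0.00248 and 0.00435, and the adjusted p was 0.418, 0.374, 0.491, 0.575 and 0.575 with an estimated correlation. The T cell and intraepithelial lymphocyte list lost its call without WT mouse 7 (median 0.34) or KO mouse 5 (0.26), with a median of 1.06 without WT mouse 1. The interferon response list lost its call without WT mouse 1 (0.08) or 7 (0.08) or KO mouse 5 (0.06), and the cholesterol biosynthesis median was 0.11 without WT mouse 7.

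Dissociation stress genes were lower in KO GFP-low cells (median -0.19, or -0.0436 when scaled by library totals; 19 of 26 below 0), with the heat shock genes Hspa1b (-1.48 ± 0.43) and Hspa1a (-1.45 ± 0.52). Unfolded protein response genes had a median of -0.10 (0.05 when scaled by library totals), with Canx at -1.11 ± 0.29. Circadian clock genes had a median of -0.21 (-0.0557 when scaled by library totals), with Per3 at -0.80 ± 0.31. Camera gave 0.00561, 0.00561 and 0.0231 for these 3 lists, and the adjusted p was 0.575 for each with an estimated correlation. S phase (0.09, or 0.25 when scaled by library totals; Gins2 0.24 ± 0.10), glycolysis (0.10, or 0.25; Bpgm 0.15 ± 0.11) and ribosomal protein genes (-0.07, or 0.08 when scaled by library totals; Rpl17 -0.18 ± 0.11) also passed at the preset correlation, and the adjusted p was 0.7102, 0.575 and 0.835 with an estimated correlation. Adjusted over the list alone, 1 stress gene fell and 0 genes of the other 5 lists passed. Single libraries ended the calls of these 6 lists: dissociation stress without WT mouse 1 (median -0.15) or 6 (-0.00969), unfolded protein response without WT mouse 8 (-0.02) or KO mouse 2 (-0.08), and S phase without WT mouse 8 (0.06) or KO mouse 2 (0.03) or 6 (0.04). The circadian clock call was lost without WT mouse 1, 6 or 8 or KO mouse 3, 5 or 6 (-0.25 to -0.11), glycolysis without WT mouse 6, 7 or 8 or KO mouse 2, 3, 4 or 5 (0.03 to 0.10), and ribosomal protein without WT mouse 6, 7 or 8 or KO mouse 3 or 4 (-0.06 to -0.03). Larger values came without WT mouse 7 (S phase 0.17, dissociation stress -0.28), KO mouse 4 (circadian clock -0.35) and KO mouse 5 (S phase 0.14, ribosomal protein -0.12). Myeloid (adjusted p = 0.984) and mitochondrially encoded genes (0.857) did not pass. Median, mean and test differed in sign in the goblet, innate defence, secretory progenitor and Notch lists, none of which passed. By exact permutation of list means (n = 5 per group), the Wnt list (p = 0.0159) was under 0.05 before adjustment, and 0 of 31 lists were after it.

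The last comparison asked whether the KO effect differed between GFP-low and GFP-high cells. Of 11296 genes edgeR called 0 (353 at an unadjusted p under 0.05, smallest adjusted p 0.9999), DESeq2 0 and limma-voom 0. These fits did not pair the populations of a mouse. With a block by mouse, edgeR called 0 genes and 777 had an unadjusted p under 0.05. The smallest p-values belonged to Egfl7 (1.49 ± 0.33), Uri1 (-0.58 ± 0.13), Fam57a (0.78 ± 0.20), Slc4a1ap (-0.59 ± 0.17) and 2900026A02Rik (-0.45 ± 0.13), none of which passed. Enteroendocrine genes had the smallest list p, with GFP-low minus GFP-high scores of 2.27 ± 0.974 in WT and 3.02 ± 0.546 in KO mice (SD, n = 5; camera adjusted p = 4.28e-11; adjusted p = 0.792 with an estimated correlation). Of 31 lists 11 passed at the preset correlation and 0 with an estimated correlation, and the lowest adjusted p was 0.650 by exact permutation of the mice. Across genes, the KO effects in the 2 populations correlated with r = 0.335, and 77 of 126 splits of the 10 mice gave as large a correlation (exact permutation p = 0.611, one-sided).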

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

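The tests for Arhgef10, for KO mouse 4, for carried GFP-low cells, for the genotype effect on secretory lists, and all counts over other splits were chosen after the result was seen. Of 232 groups of 5 libraries, 18 held a library far from the other 4, by a gap above 0.71 of the group's range. Chance flags about 1 in 20 groups.

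Arhgef10 was lower in KO GFP-low cells, and 1 WT GFP-low library (mouse 1) stood apart from its group with a log2 CPM of 1.64. A cause in 1 sorted population alone was argued against by the fall in GFP-high cells (log2 fold change -1.56), and a difference between the sexes by the call kept with sex as a covariate (edgeR adjusted p = 0.00165; 1.25e-16 to 0.0617 over the alternatives). A variant segment of chromosome 8 stayed open, since 4 of 23 tested genes within 2 Mb had p under 0.05 against 6.30% of other genes (Fisher's exact test p = 0.0537). As Itgb7 lies on chromosome 15 and its transcript is not analysed here, a direct effect of the KO and a strain difference cannot be told apart.

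The 64 tested genes of the enteroendocrine, goblet and tuft lists had a median log2 fold change of -0.62 in KO GFP-high cells, although 0 passed over all genes and the lists' adjusted p was 0.343, 0.463 and 0.343 with an estimated correlation. Scaling of the libraries was argued against, since the highest median over other scalings was -0.58. Carry-over of fewer GFP-low cells into KO GFP-high libraries stayed open: relative to the enterocyte score the difference was -0.487 (exact permutation p = 0.198). Mean scores were 3.90 ± 0.455 in WT and 3.30 ± 0.2995 in KO libraries (SD, n = 5, exact permutation p = 0.0397). Allowing for the choice of 3 lists, a step added after that value was seen, the permutation p was 0.484. That step set the 3 lists against the 3 most extreme lists of every split, so 0.484 is an upper limit. Lower secretory transcripts in KO GFP-high cells therefore remain a hypothesis that these 10 libraries cannot decide.

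The MHC class II list was higher in KO cells at the preset correlation, without a member passing over all genes (adjusted p = 0.343 in GFP-high and 0.374 in GFP-low cells with an estimated correlation), and KO mouse 4 stood apart in GFP-high (score 7.28) and GFP-low cells (6.16). That mouse as the whole source was argued against: without it 78.7% of the difference in mean score was left in GFP-high and 71.6% in GFP-low cells. The median log2 fold change moved further in GFP-low cells, from 0.91 to 0.49 without that mouse, and from 0.85 to 0.60 in GFP-high cells. Immune cells carried through the CD45-negative gate stayed open, since MHC class II and T cell scores of 10 GFP-high libraries correlated with r = 0.212 around their group means (permutation p = 0.579), and with r = -0.468 without the 2 farthest libraries. Without centring on the group means, which leaves the genotype difference in, r was 0.426. The T cell score does not measure B or myeloid cells, so these correlations cannot decide whether such cells passed the gate. Cd74 was at 209 ± 130 CPM in WT and 478 ± 205 CPM in KO GFP-high cells (n = 5). Immune markers were at 6.75 and 13.4 for Gzma, 1.69 and 2.21 for Coro1a and 4.45 and 4.62 for Cd68. Cd3g was at 0.66 and 1.40 and Fcer1g at 0.377 and 1.15 CPM. An epithelial response to the loss of Itgb7 in lymphocytes was not tested and stays open.

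The other outlying libraries were as follows. In WT GFP-high cells, mouse 6 had a Wnt list score of 5.59 and mouse 7 a log2 CPM of 12.02 for Olfm4. In KO GFP-high cells, mouse 5 had an enteroendocrine score of 3.06, mouse 2 a proximal score of 4.23 and mouse 6 a log2 CPM of 5.50 for Fstl1. In WT GFP-low cells, mouse 1 had an oxidative phosphorylation score of 8.00 (8.27 was the lowest of the others), mouse 7 a myeloid score of 1.96 and mouse 6 a log2 CPM of 0.81 for Gif. In KO GFP-low cells, mouse 2 had low goblet (7.34), Paneth (8.22) and secretory progenitor (3.76) scores and a log2 CPM of 5.67 for Capn9. In the same group mouse 6 had a glycolysis score of 6.79, and mouse 5 a score of 5.36 for neighbours of Itgb7 and a log2 CPM of 0.18 for Slc1a2.

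The KO effect differed between GFP-low and GFP-high cells in 11 lists at the preset correlation and in 0 with an estimated correlation (lowest adjusted p = 0.125). As GFP-low minus GFP-high, the difference in score was 0.75 for enteroendocrine, -0.65 for Paneth, 0.37 for goblet, 0.49 for tuft, 0.35 for secretory progenitor and -0.20 for stem cell genes. It was 0.12 for S phase, -0.0867 for G2/M, -0.22 for enterocyte, -0.19 for Wnt and -0.22 for fatty acid oxidation and PPAR target genes.

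Other splits of the 10 libraries were counted in 100 of 126 possible divisions. Genes changed between genotypes in GFP-high cells numbered 0 by edgeR (1150 at an unadjusted p under 0.05; DESeq2 145, limma-voom 0), so the count of 100 of 100 splits was fixed in advance and tests nothing (highest other 45). In GFP-low cells 1 gene was called, and 5 of 100 splits called as many (highest other 11), so this count cannot exclude chance there. The other splits that called a gene were uneven by 2 or 4 mice with Y-linked counts, whereas the real split was even. These splits therefore do not hold sex constant. The GFP-high split with 45 genes was even for sex, and 8 of 100 GFP-high splits called any gene. What set the split with 45 genes apart was not tested. The GFP-low split with 11 genes was uneven by 4 mice with Y-linked counts, so its calls cannot be told apart from sex. For GFP-low against GFP-high, 1 of 100 splits, the real one, called as many in WT (4901, highest other 0). The same held in KO mice (5707, highest other 271). Every other split mixed the populations within its groups, which adds spread and makes calls unlikely. Of 16 splits that exchanged populations only within mice, the real one alone called genes (highest other 0 in both genotypes). With 16 splits the share cannot fall under 0.05, so this count alone cannot exclude chance. The interaction also called 0 genes by edgeR (353 at an unadjusted p under 0.05; DESeq2 0, limma-voom 0), so its 100 of 100 splits test nothing either. Counts of lists at the preset correlation were reached by 47 of 100 splits in GFP-high (12; highest other 18) and 4 of 100 in GFP-low cells (17; highest other 17). They were reached by 13 of 100 splits in WT (21; highest other 22) and 16 of 100 in KO mice (21; highest other 22) for GFP-low against GFP-high. Other splits passed many lists at this correlation (medians of 11, 13, 15 and 14 in the same order), so this count cannot show whether the lists of GFP-low against GFP-high cells moved by chance. For the genotype lists chance is not taken as excluded in either population, since 0 passed with an estimated correlation and 0 by exact permutation.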

How the results depend on the processing

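Library totals, the sex covariate and permutation of list means were tests chosen after the data were seen. Genes called between GFP-low and GFP-high cells ranged from 4268 to 6083 in WT and 5189 to 6516 in KO mice over all settings, and the interaction kept 0. Of 73 named genes followed in WT, Ly6e, Ndufb7 and Ndufs5 lost their call with library totals, and of 70 in KO mice 0 did. The replicate block, pairing populations of a mouse, called 5845 and 6464 genes there, with 4877 of 4901 and 5693 of 5707 calls kept, and 22 lists in each genotype, with MHC class II added in both (medians -1.06 and -1.04). The replicate block with an estimated correlation, also chosen after the data were seen, passed 1 list in WT and 6 in KO mice; the cause was not tested. With an estimated correlation the passing lists fell to 6 in WT and 5 in KO mice, and to 0 in both genotype comparisons. Without a block, fry passed 23 lists in WT and 27 in KO mice, and 0 in both genotype comparisons. Its form for changes of mixed direction passed 6 lists between genotypes in GFP-high and 3 in GFP-low cells. Exact permutation of list means passed 21 in WT and 27 in KO mice for GFP-low against GFP-high, and 0 in both genotype comparisons. For GFP-low against GFP-high it exchanged libraries freely and ignored the pairing by mouse. Exchanges within mice allow 16 splits, too few for a p under 0.05, so the 21 and 27 rest on the ignored pairing. DESeq2 called 145 genes between genotypes in GFP-high and 12 in GFP-low cells; the cause was not tested. Leaving out 1 library gave 0 to 1 and 1 to 2 genes.

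Between genotypes, WT and KO mice shared only the numbers 3 and 6, whose libraries did not deviate together (r from -0.105 to -0.0764), so the numbers are not a pairing. Every other number was held by a WT or a KO mouse alone. A replicate block on the numbers therefore left only the mice numbered 3 and 6 to estimate the KO effect. This block called 122 genes in GFP-high and 36 in GFP-low cells. Arhgef10 missed the threshold (edgeR adjusted p = 0.0617, with 1.25e-16 its lowest over 20 settings). Under this block signs reversed in GFP-high cells for Lgr5 (-0.0544), Gzma (-0.17), Mvk (-0.00348) and the ribosomal protein (0.0525) and T cell (-0.0708) medians. In GFP-low cells they reversed for H2-DMa (-0.19), Psmb9 (-0.0457) and the MHC class II (-0.24) and interferon response (-0.0186) medians. These values under the block do not compare all KO with all WT mice. In simulation 82% of 2-fold changes were recovered in each genotype comparison, but 40% (GFP-high) and 22% (GFP-low) of 1.5-fold changes, so small changes of single genes would mostly be missed at this depth and number of mice.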

Other observations

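The test of gene positions was chosen after the result was seen; the tests of gene families and of summed counts were not. Between GFP-low and GFP-high cells, 12 of 49 symbol prefixes with at least 20 tested genes held a larger share of rises or of falls than other genes in both genotypes, at adjusted p under 0.05. That test takes genes as independent, which co-regulated genes are not. Genes of the secretory pathway with the prefix Sec were higher in 18 of 24 cases in WT and 17 of 24 in KO mice (medians 0.80 and 0.63, or 0.44 and 0.37 when scaled by library totals), and Cyp genes, mostly oxidases, in 16 and 15 of 25 (1.21 and 1.19). Solute carriers (Slc) were higher in 82 and 100 of 208 cases (medians 0.28 and 0.35), although with library totals the medians were -0.07 and 0.09. Rab trafficking GTPases were higher in 20 and 25 of 51 cases (medians 0.37 and 0.31, or 0.00284 and 0.06 with library totals). Atp genes were higher in 26 and 32 of 58, with medians of -0.06 and 0.02 when scaled by library totals, and Tmem genes in 55 and 60 of 162, with medians of -0.19 and -0.06 in that scaling.

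Lower families were ribosomal proteins (Rpl, 30 and 36 of 48 in WT and KO mice; Rps, 23 and 26 of 44), the centrosomal Cep genes (17 and 20 of 33), the kinesins (Kif, 12 and 14 of 26), Wdr genes (25 and 23 of 49) and zinc finger genes (Zfp, 77 and 107 of 273). The ribosomal protein list, tested as 1 group, had an adjusted p of 0.497 in WT and 0.397 in KO mice with an estimated correlation. Medians of Cep genes were -0.49 and -0.54, and those of Zfp genes -0.29 and -0.32. With library totals the medians of lower families were further below 0, at -0.85 and -0.79 for Cep, -0.64 and -0.57 for Zfp, -0.76 and -0.77 for Kif, -0.77 and -0.65 for Rpl, -0.73 and -0.62 for Rps and -0.64 and -0.51 for Wdr genes.

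A KO effect common to both populations was sought by summing the counts of each mouse. Of 11296 genes 1 passed, Arhgef10 (log2 fold change -1.91 ± 0.19, edgeR adjusted p = 0.00258; 815 genes at an unadjusted p under 0.05), so summing brought no further gene past the threshold. Genome segments that differ between mice would cluster genes by position. Of 365 genes with p under 0.01 in GFP-high cells, 166 had another within 1 Mb, against a mean of 156 in random draws (permutation p = 0.207), which leaves such segments open.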
